A study of Drosophila melanogaster with 54 samples.

How the data were processed

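RNA from staged Drosophila melanogaster embryos was measured on 54 one-colour Agilent arrays. The assay was translating ribosome affinity purification, in which polysomes that carry a GFP tag are pulled down from an embryo lysate together with the RNA bound to them. Each pull-down (IP) was set against an input sample, in the usual sense of that word the RNA of the lysate before the pull-down. The labels name 3 muscle populations (S59, lms and Duf), 3 windows of age (7 to 10, 10 to 13 and 13 to 16 h after egg laying), 2 fractions (IP and input) and 3 replicates, which made 18 groups of 3 arrays. Every array was placed in its group by its title. The labels do not say that replicates came from separate embryo collections, so p-values measure only the spread between these samples, which may be technical. Slide and scan date were not given in the sources used here, so no batch was tested.

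The embryos were aged at 25 degrees and the RNA was purified with Trizol, per the labels' protocols. From 10 ng of RNA, Cy3 targets were made with a low-input whole-transcript kit and hybridized to arrays of the 8x60K format, also per the labels' protocols. The authors deposited 1 value table of linear intensity for 44921 numbered probes. Background correction, software and the probe filter are not given in the sources used here. The values themselves show a normalization: within each set of 6 arrays (1 population in 1 window, 3 IP and 3 input), the sorted intensities were identical at all 44921 ranks in 8 of the 9 sets. They differed between sets, so the deposited intensities had been quantile normalized within each set and not across sets. IP and input arrays of a set were thus brought to 1 distribution. Enrichment and depletion are therefore relative to the other probes, and near-equal numbers of each largely follow from this step. The median intensity of a set ran from 3.64 to 14.4. In S59 at 10-13h, 19.5% of intensities under 1000 were whole multiples of a sixth within 0.01, against 1.85% to 2.13% in the other sets, so this set had been handled in another way whose nature stayed unknown.

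The remaining set, S59 at 13-16h, shared its sorted values at only 1513 ranks. In it 57 probes were written in another number format and looked not normalized: input replicate 3 over the mean of replicates 1 and 2 had a median ratio of 2.44 in them and 0.989 elsewhere. Without these 57 probes and 1 probe with a missing value, the set shared 43853 of 44863 ranks. All 58 were left out of every array. Another 313 probes were left out because they rose and fell together on all 54 arrays, by up to 7.47 on the log2 scale. They were found among 10180 probes with an SD over 1 on the log2 scale. The probe with the most neighbours at r over 0.98 gave a common profile, and every probe that followed it at r over 0.85 was removed. This removal was decided after the data were examined and was no part of the planned analysis. The remaining 44550 probes were tested.

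No table used here pairs the probe numbers with genes, and no gene name is given. The 26 gene lists fixed before the data were examined, the tests on them, the listed genes of the naming rule and the alternative that averages the probes of a gene were therefore not run. A gene can have several probes and some probes may be copies, so a count of probes is not a count of genes. The naming rule took probes past the test with the same sign in all 3 windows and a brighter fraction above the median of all probes, ranked by log2 difference. From it only the top 2 and bottom 2 probes of the Duf comparison are named, a reduction made once it was known that the probes carry no gene names.

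Intensities were taken to log2, and the 75th percentile of each array was subtracted, which moves little within a set. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without a trend) over all 54 arrays and 18 group means, with 36 residual degrees of freedom and 2.36 prior degrees of freedom. All groups thus shared 1 estimate of spread per probe. P-values were two-sided and Benjamini-Hochberg adjusted over the 44550 probes within each comparison, with a threshold of 0.05. Called means past this threshold, enrichment means the log2 difference of IP over input within a set, and depletion means an enrichment below 0. There were 18 comparisons: IP against input in each of 9 sets, the mean of the 3 windows in each population, the differences between populations in that mean, and the change of enrichment from 7-10h to 13-16h in each population. Every one is a difference within sets or a difference of such differences. The 3 planned comparisons of IP levels between ages set separately normalized arrays against each other and were not run.

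The fit was tested on simulated data for 44550 probes with 200 changed. The simulated noise was independent between arrays and had 1 spread per probe in all groups. In the real sets the mean replicate variance of the log2 difference ran from 0.120 (Duf at 7-10h) to 0.271 (lms at 7-10h), and many more probes were called. The recovery and the false calls below therefore hold for the simulated setting and may differ in the real sets. For the Duf mean over windows it recovered 10.4% of changes of 0.50 on the log2 scale, 55.2% of changes of 1.00 and 97.0% of changes of 2.00, with 8 false calls. For Duf at 13-16h alone it recovered 28.4% of changes of 1.00 and 56.1% of changes of 2.00. For S59 against Duf it recovered 29.9% and 87.9% of these sizes, and for the S59 change with age 5.97% and 40.9%. The number of arrays limits the precision. No detection flags were used here, and between 37.6% and 51.8% of the intensities of a set lay below 2 times its lowest intensity. A difference that rests on such values is poorly measured in size.

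The alternatives fixed before the data were examined were quantile normalization across all 54 arrays, leaving out the dimmest 33.3% of probes, an intensity trend in eBayes, fitting only the arrays of the comparison, the replicate number as a block, and leaving out each array in turn. Means without the 7-10h window, the fit with the 313 co-moving probes and the replicate block within the arrays of a single set were added after the data were examined.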

Results

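The data were 54 arrays of embryonic RNA from 3 somatic muscle populations. S59 is an older name of slouch, and lms is short for lateral muscles scarcer; both genes encode homeodomain transcription factors of subsets of body wall muscles. Duf, or Dumbfounded, is a cell adhesion receptor of the founder cells from which the body wall muscles arise. Each population was sampled at 7-10h, 10-13h and 13-16h after egg laying, with 3 IP and 3 input arrays in each window. Across the 44550 probes, the median correlation between replicates of a set ran from 0.928 to 0.984 for IP and from 0.964 to 0.983 for input. Between IP and input arrays of a set it ran from 0.911 to 0.956. In lms at 7-10h the IP replicates agreed less with each other (median r 0.928) than with the inputs (median r 0.952). The lowest agreement with its group was that of lms IP replicate 1 at 7-10h, with a mean r of 0.926 against 0.955 and 0.957 for the other arrays of that group. These correlations are across probes, which are not independent replicates.

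The first question was which RNA was bound to tagged ribosomes above or below its level in the input. In the Duf population, averaged over the 3 windows (9 IP and 9 input arrays), 12992 probes (29.2%) were called, of which 6519 were enriched and 6473 depleted. At least 2-fold enrichment was reached by 3389 of them and at least 2-fold depletion by 2913. In S59, 6016 probes were enriched and 6766 depleted, 2124 and 2507 of them by at least 2-fold. In lms, 5419 were enriched and 6171 depleted, 1744 and 2338 of them by at least 2-fold. With IP and input normalized together, the median log2 difference over all probes was -0.023 in Duf, 0.015 in S59 and 0.033 in lms. The balance of enriched and depleted probes is thus not a measured result. The median size of a called difference was 0.98 on the log2 scale in Duf, 0.84 in S59 and 0.82 in lms, with a median standard error of 0.22. The called probes were mostly bright: in Duf the enriched ones had a median brightness percentile of 82.6 and the depleted ones 79.3, against 35.9 for probes not called.

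Probe 62658 came first under the naming rule, with a Duf enrichment of 7.62 ± 0.39 (log2, SE, n = 9 IP and 9 input arrays; limma adjusted p = 1.66e-19). Its enrichment was 4.70 in S59 and 4.72 in lms, both with an SE of 0.39. Probe 814 was enriched by 7.09 ± 0.26 in Duf (limma adjusted p = 4.96e-24), by 4.88 in S59 and by 4.08 in lms. In Duf at 13-16h its mean intensity was 9243 ± 1290 (SD, n = 3) in IP and 366.8 ± 82.6 (SD, n = 3) in input. The Duf inputs of both probes at 7-10h, at 8.56 ± 5.91 and 8.96 ± 4.70 (SD, n = 3), and that of probe 62658 at 10-13h, at 11.1 ± 7.79 (SD, n = 3), varied widely between arrays, so the size and the rank of these log2 differences are uncertain. At the other end, probe 34851 stood at -7.48 ± 0.29 in Duf (limma adjusted p = 2.68e-23), -7.18 in S59 and -6.73 in lms. Its Duf intensity at 13-16h was 60.5 ± 12.1 (SD, n = 3) in IP and 13231 ± 294.7 (SD, n = 3) in input. Probe 35118 stood at -6.55 ± 0.38 in Duf (limma adjusted p = 1.12e-17), -4.24 in S59 and -5.65 in lms, and its size is uncertain too, since its Duf IP intensities were 9.86 ± 3.51, 9.12 ± 4.04 and 7.16 ± 4.47 (SD, n = 3) from the first to the last window.

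**Figure D1:**
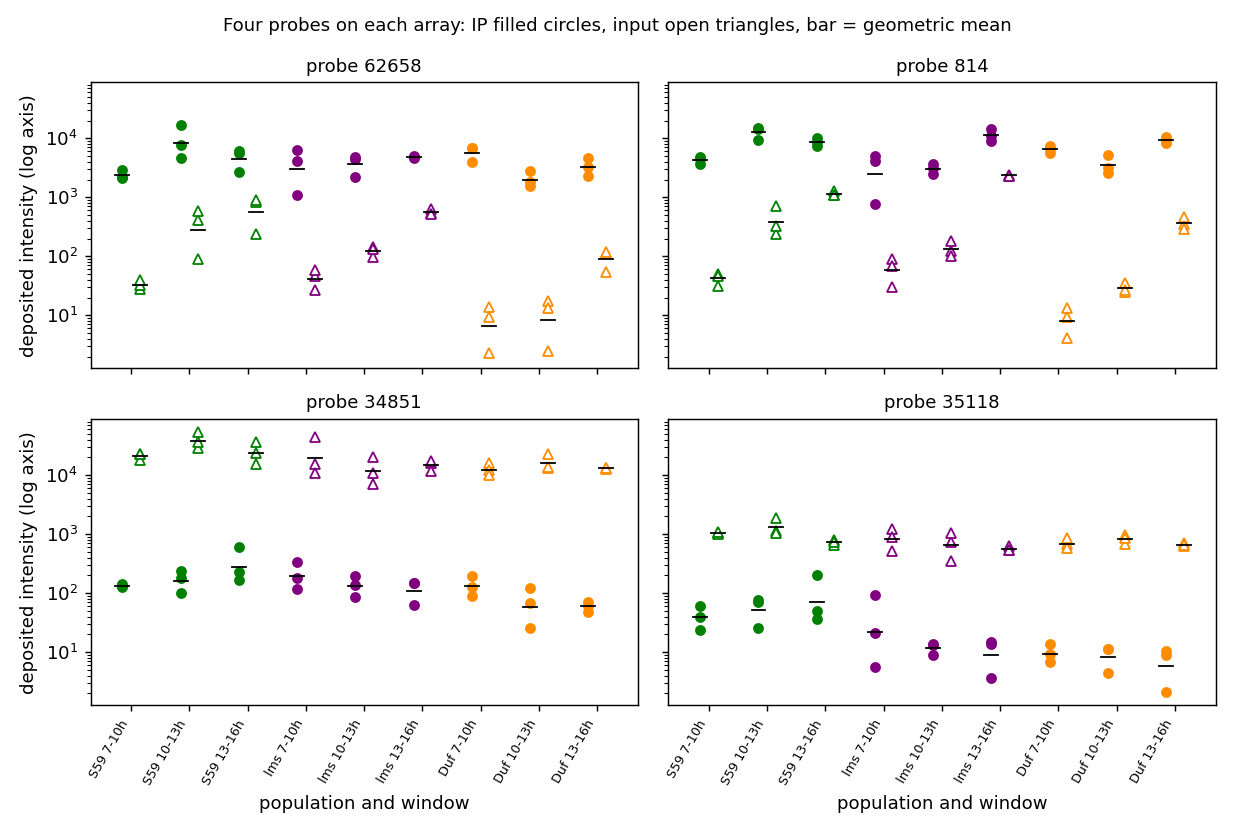
Deposited intensity (arbitrary units, log axis) of 4 probes on each array, by population and window; filled circles are IP, open triangles input, and bars geometric means of 3 arrays. Probes 62658 and 814 lay higher in IP than in input in all 9 sets, and probes 34851 and 35118 lower.

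By window, the number of called probes in each population was lowest at 7-10h and highest at 13-16h in the fit over all groups. In Duf, 2792 probes were enriched and 2120 depleted at 7-10h, 5003 and 4157 at 10-13h, and 6032 and 5242 at 13-16h. On its own 6 arrays the Duf set at 7-10h gave 2735 enriched and 2952 depleted, so there the majority turned. In S59 the enriched and depleted counts were 2207 and 2816 at 7-10h, 3339 and 3272 at 10-13h, and 5216 and 4995 at 13-16h. In lms they were 1397 and 740 at 7-10h, 3017 and 2578 at 10-13h, and 5794 and 5770 at 13-16h. Among all 44550 probes, called or not, between 14.97% (lms at 7-10h) and 41.3% (lms at 13-16h) had no overlap between the 3 IP and the 3 input arrays, against 10% by chance. Fitted on their own 6 arrays, lms at 7-10h had 194 called probes instead of 2137, S59 at 10-13h had 4040 instead of 6611, and S59 at 13-16h had 3718 instead of 10211, against 5345 for S59 at 7-10h. In these 3 sets every IP and input array of the same replicate number deviated together at r over 0.1, and with that number as a block on the same 6 arrays, a fit added after the data were seen, limma called 0 probes in lms at 7-10h (4947 at unadjusted p under 0.05) and 2544, 4412 and 6720 in S59 from the first to the last window.

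**Figure D2:**
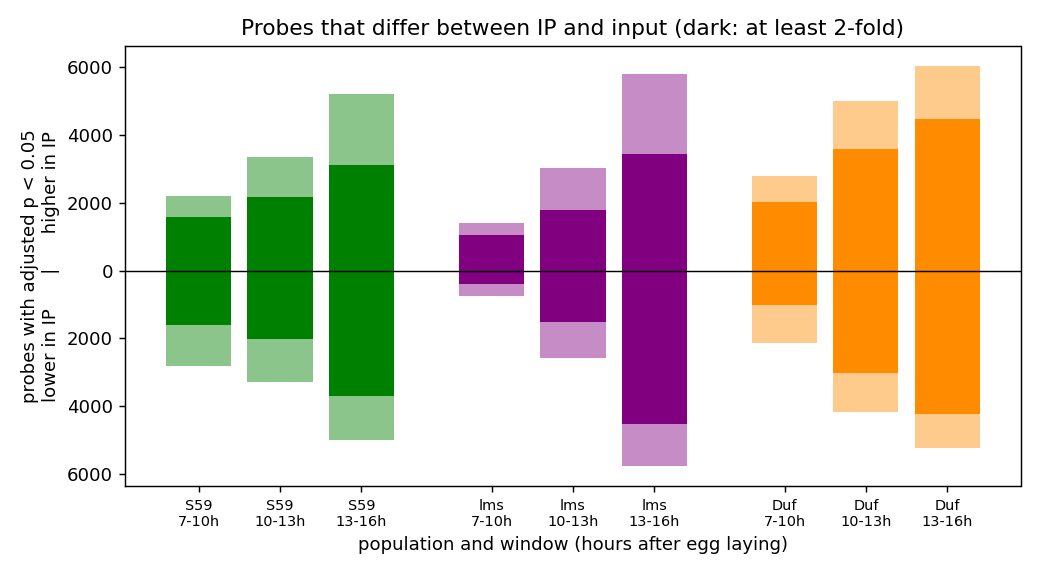
Number of probes called by limma (adjusted p under 0.05) in IP against input for each population and window, with enriched probes above and depleted probes below the line; dark parts are differences of at least 2-fold. The tallest bars belong to the 13-16h window, with 6032 enriched probes in Duf and 5770 depleted probes in lms.

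Many probes kept their direction through development. In Duf, 2043 probes were enriched and 1325 depleted in all 3 windows, against 42.5 and 23.3 if the windows were independent. In S59 these numbers were 1246 and 1320 (19.4 and 23.2 if independent), and in lms 845 and 409 (12.3 and 5.55 if independent). With each set fitted on its own arrays, also chosen after the data were seen, they were 640 and 322 in S59 and 153 and 8 in lms, and with the block as well none in lms, where no probe was called at 7-10h. Across probes, the enrichment at 7-10h correlated with that at 13-16h at r = 0.555 in Duf, 0.454 in S59 and 0.371 in lms. Neighbouring windows correlated at 0.696 and 0.749 in Duf, 0.633 and 0.694 in S59, and 0.542 and 0.605 in lms.

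The second question was whether the populations held the same ribosome-bound RNA. Enrichment in all 3 populations was found for 3321 probes and depletion in all 3 for 3617, against 107 and 136 if the lists were independent. The populations share no arrays, but they share 1 estimate of spread per probe, and called probes were mostly bright. Counts for independent lists are therefore a low baseline, here and for the windows and the age changes. Duf and S59 shared 4056 enriched probes, Duf and lms 3969, and S59 and lms 3617. Probes called in opposite directions numbered 147 between S59 and Duf, 147 between lms and Duf and 100 between S59 and lms, against 1864, 1690 and 1656 for independent lists. The mean enrichment correlated across probes at r = 0.773 between S59 and Duf, 0.748 between lms and Duf and 0.7496 between S59 and lms. Among the probes called in Duf, 91.7% had the same sign in S59 and 91.8% in lms, and among all 44550 probes 66.2% and 65.5%.

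**Figure D3:**
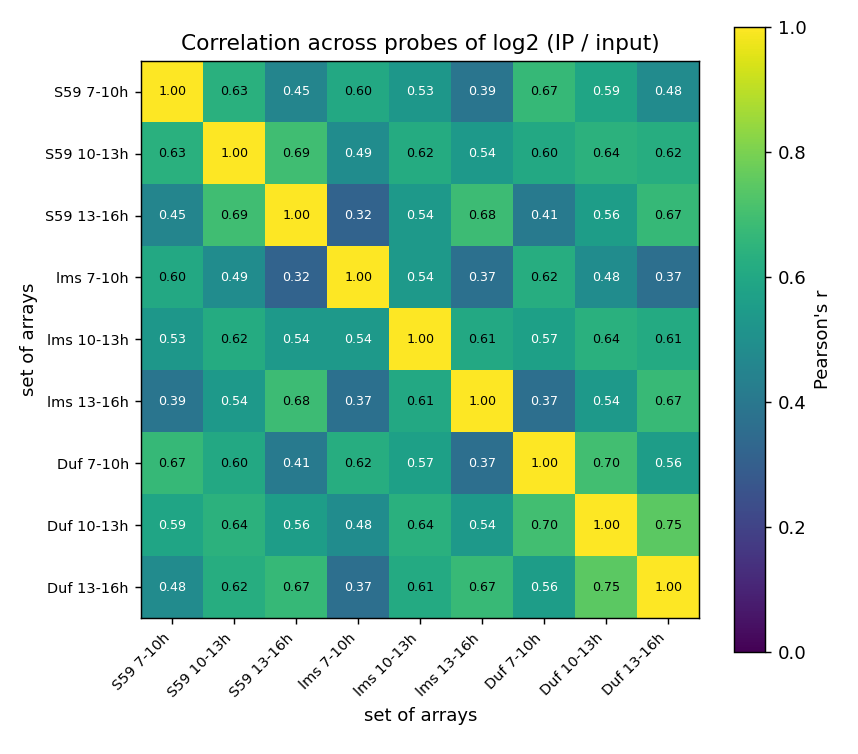
Pearson's r across 44550 probes of the log2 difference of IP over input between the 9 sets of arrays, by population and window. Values between populations in the same window ran from 0.602 to 0.685, and values within a population from 0.371 to 0.749.

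The difference in enrichment between populations was tested directly on the means over the 3 windows. Between S59 and Duf, 3886 probes differed, with enrichment higher in S59 for 1228 and higher in Duf for 2658. Between lms and Duf, 3834 differed, 1310 higher in lms and 2524 higher in Duf. Between S59 and lms 1027 differed, 435 higher in S59 and 592 higher in lms. The median size of a called difference was 0.78 on the log2 scale for S59 against Duf, 0.84 for lms against Duf and 1.22 for S59 against lms. These medians depend on how many probes passed the threshold and do not rank the pairs. Over all probes the SD of the difference was smallest for S59 against lms, at 0.483, against 0.510 for S59 against Duf and 0.526 for lms against Duf. Most probes that were higher in Duf were enriched there, 2263 of the 2658 set against S59 and 2298 of the 2524 set against lms. Of the probes higher in lms than in Duf, 396 were enriched in lms and 969 were depleted in Duf.

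Some probes set a single population apart. In Duf 1576 probes were enriched and also above both other populations, which was 24.2% of its enriched probes. Their median enrichment was 1.32 on the log2 scale in Duf, 0.56 in S59 and 0.55 in lms. Once the Duf enrichment was multiplied by the slopes of the main axes, 476 of these 1576 probes were still above both, a count added after the data were seen. In S59 there were 215 such probes (3.57%), with medians of 2.39 in S59, 0.22 in lms and 0.38 in Duf. In lms there were 190 (3.51%), with medians of 1.71 in lms, -0.45 in S59 and -0.21 in Duf. Both comparisons of a population use its own arrays, so part of any overlap may come from the shared arrays. Probes above both others numbered 1634 in Duf, 236 in S59 and 291 in lms, against 151, 11.99 and 17.4 for independent lists, which these lists are not. There were none in 20 simulated draws of unchanged groups, but these draws made at most 2 calls in the 3 comparisons together. They could therefore not show how much overlap the shared arrays give.

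**Figure D4:**
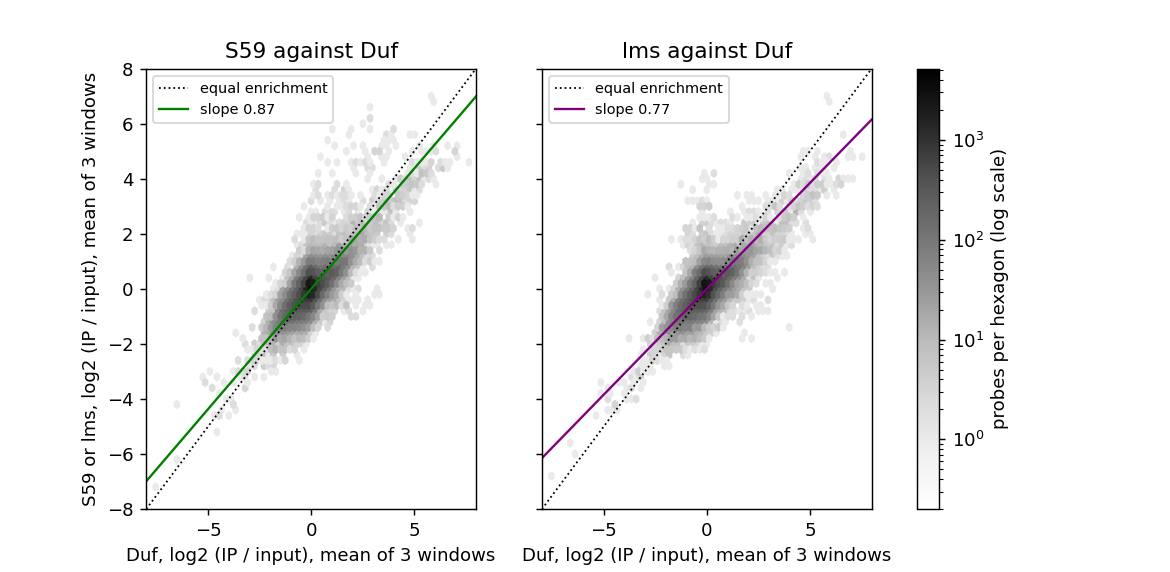
Mean log2 difference of IP over input per probe in S59 (left) and lms (right) against Duf, with shading for the number of probes, a dotted line of equal enrichment and a solid line for the main axis of the points. The main axis had a slope of 0.874 for S59 and 0.769 for lms.

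The third question was how enrichment changed with age, tested as enrichment at 13-16h minus enrichment at 7-10h. In Duf it rose for 2055 probes and fell for 1909, in lms it rose for 1618 and fell for 2166, and in S59 it rose for 1242 and fell for 1180. The median rise was 1.21 in Duf, 1.36 in lms and 1.49 in S59 on the log2 scale, and the median fall -1.90, -1.97 and -2.09, with a median standard error of 0.53. These are medians of called probes and do not rank the populations. Over all probes the SD of the change was 0.865 in Duf, 0.947 in lms and 0.883 in S59. Most of the probes that rose were enriched at 13-16h, 1896 in Duf, 1402 in lms and 891 in S59. Most of those that fell were depleted at 13-16h, 1355 in Duf, 1718 in lms and 762 in S59. At 7-10h, 189, 106 and 364 of those that rose were depleted in Duf, lms and S59, and 545, 377 and 450 of those that fell were enriched. The 13-16h arrays also defined the rise or fall, and more probes were called in that window. These counts therefore do not show that the change lay at 13-16h. A change from called depletion at 7-10h to called enrichment at 13-16h was found for 79 probes in Duf, 13 in lms and 74 in S59, and the opposite change for 67, 52 and 84. The 10-13h value lay between the others for 85.7% of the probes that rose in Duf, 90.9% in lms and 94.3% in S59. These probes were selected for a gap between 7-10h and 13-16h, which by itself favours a value between them. No share over all probes was taken, so a gradual change is not shown.

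The age changes were partly shared. Enrichment rose in all 3 populations for 308 probes and fell in all 3 for 512, against 2.08 and 2.46 for independent lists. Duf and lms shared 705 probes that rose and 1070 that fell, S59 and lms 470 and 648, and S59 and Duf 409 and 637. Opposite changes were called for 6 probes between Duf and lms, 11 between S59 and lms and 4 between S59 and Duf, against 169, 103 and 108 for independent lists. Fitted on the arrays of the comparison alone, the S59 count was 1288 instead of 2422 and the lms count 2382 instead of 3784.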

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

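The intensity trend, the weaker pull-down, the deviating array and the splits of the arrays were fixed as tests before their results were seen, whereas the test of the pooled spread, the division of the normalization test by population, that of the lms pull-down test by window and the test of control RNA under other observations were chosen afterwards. A difference of effects between populations or ages was called for probes in 6 comparisons. Enrichment differed between S59 and Duf for 3886 probes, between lms and Duf for 3834, and between S59 and lms for 1027. From 7-10h to 13-16h it changed for 2422 probes in S59, 3784 in lms and 3964 in Duf. In each of these, 1 of 100 splits of the same arrays, the real one, called as many probes, so a random assignment of single arrays can be excluded. The splits treat arrays as separate units. Whether replicates are separate embryo collections is not known, so differences between collections or between sets of arrays are not excluded. The highest other splits called 55, 2 and 12 probes for the population differences and 830, 1827 and 303 for the age changes. The same held for IP against input averaged over windows, with 12782 in S59 (highest other split 6763), 11590 in lms (7697) and 12992 in Duf (7569). In a single window 3 arrays against 3 make 10 splits, too few for a share under 0.05. There the real split gave 5023, 6611 and 10211 probes in S59 from the first to the last window, with 149, 173 and 4149 in the highest other. For lms the real values were 2137, 5595 and 11564 (highest other 815, 43 and 560), and for Duf 4912, 9160 and 11274 (7, 23 and 35).

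The enrichment of the same probes in the 3 populations had 2 technical explanations. A trend of the log2 difference with brightness, common to all pull-downs, was argued against, since the lowest correlation of mean enrichment between populations was 0.742 after the trend had been removed and 0.748 before. RNA that any pull-down enriches, whatever ribosomes are tagged, cannot be told apart from RNA shared by the muscle populations for the 3321 probes enriched in all 3. No pull-down from embryos without tagged ribosomes was used here, and this keeps the question open. RNA common to muscles of different identity is 1 biological explanation, and it was not tested. Since the body wall muscles arise from founder cells with Duf, the Duf population may include S59 and lms muscle cells. Sharing with Duf therefore need not mean sharing between distinct muscles, and this was not tested either.

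More probes were called at 13-16h than at 7-10h in each population in the fit over all groups. In S59 the pooled spread stays open as a cause, since with each set fitted on its own arrays the ratio of called probes was 0.696 instead of 2.03, but 2.64 once the replicate number was added as a block. In lms and Duf the fit on own arrays left a ratio of at least 1.85 (1.775 in Duf with the block), and bringing all 54 arrays to 1 distribution left at least 2.54 (1.58 in S59, and 1.48 with the 313 co-moving probes kept), which argues against separate normalization as the whole cause. Leaving out lms IP replicate 1 at 7-10h, the array that agreed least with its group, gave 1918 probes in lms at 7-10h, still under the 4912 of Duf and 5023 of S59. With 1 array of the set left out as well, Duf had 3323 to 4804 at 7-10h and S59 3828 to 4654. The lms number was under these too, so that array is not the whole cause of the low lms number. The SD of enrichment over probes, corrected for replicate variance, was 1.12 times as large at 13-16h in S59, 1.86 times in lms and 1.21 times in Duf; a change of the muscles with age stays open in all 3 populations and was not tested.

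Most probes that set S59 or lms apart from Duf had the higher enrichment in Duf. A weaker pull-down was taken to shrink all log2 enrichment by 1 factor, and the slopes against Duf were 0.874 in S59 and 0.769 in lms. This factor is an assumption. The slopes were taken with replicate variance left in. That variance was larger in S59 (0.164 to 0.246) and lms (0.169 to 0.271) than in Duf (0.120 to 0.151), which can raise the slopes. Shrinkage stronger than these slopes was not tested. A weaker pull-down that compresses enriched and depleted probes unequally was not tested and stays open. With Duf enrichment multiplied by this slope, 2895 probes were called in S59 (959 higher and 1936 lower), 2750 of them among the 3886. Shrinkage by the factor 0.874 was thus not the whole cause in S59. In lms 1776 were called (711 higher and 1065 lower), 1620 of them among the 3834, but the windows differed. The slope was 0.760 at 7-10h (0.692 to 0.914 with single arrays left out) and 0.742 at 10-13h (0.685 to 0.825). In these windows 154 probes were called instead of 445 and 312 instead of 891, as shrinkage by 1 factor would give for most of the difference. At 13-16h the slope was 0.951 (0.906 to 1.09), a range that overlaps that of 7-10h. There 1488 were called instead of 1707 (610 higher and 878 lower). Shrinkage by the factor 0.951 was thus not the whole cause at 13-16h, and for the mean shrinkage stays open. The makeup of the populations was not tested.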

How the results depend on the processing

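In the means over windows, no named probe changed sign or lost its call under any alternative run on these means. In lms at 7-10h alone, the named probes lost their calls with the block on the arrays of the set, where no probe was called. Whether more probes were called higher or lower turned under some alternative in 8 of 18 comparisons. Means without the 7-10h window, the fit with the co-moving probes and the block in single sets were added after the data were seen. Quantile normalization and the intensity trend kept all 40 results of each. Kept means counts within 1.5 times their value, correlations within 1 SD over windows, and named probes with the same sign and call. The intensity trend cannot change correlations or log2 differences, so part of its result was fixed in advance. Leaving out the dim probes kept 38 of 40, adding the co-moving probes 39 of 40 and dropping the 7-10h window 25 of 26, the exceptions being correlations. With the co-moving probes, 4252 probes differed between S59 and Duf and 4122 between lms and Duf. Leaving out single arrays kept all 918 values; the lms change with age ranged from 2658 to 5277, and the number for lms at 7-10h from 1779 to 2926. Fitting only the arrays of the comparison moved 5 of 30 results, all downward, while others rose: 4040 for S59 at 10-13h, 3718 for S59 at 13-16h, 194 for lms at 7-10h (176 higher and 18 lower), and 1288 and 2382 for the age changes in S59 and lms; these 3 sets had the highest replicate variance of the 9, and fewer arrays leave fewer degrees of freedom. IP and input of the same replicate number deviated together with r from 0.0164 to 0.421, over 0.1 in 13 of 27 pairs and in every pair of 3 of 9 sets. Since not every pair passed 0.1, the numbers were not taken as pairing in the main fit. Yet 26 of 27 IP arrays correlated best with the input of their own number. The main fit thus leaves out a pairing that these values point to. The replicate block raised the calls to 3869 for lms at 7-10h, to 5981 (S59 against Duf), 5934 (lms against Duf) and 2012 (S59 against lms), to 4507 in S59, 6277 in lms and 6105 in Duf for age, to 682 and 1010 for rises and falls shared by all 3 populations, and to 2462 for probes enriched in Duf above both others. It kept the other 30 results by the same rules, among them correlations that the block cannot change. With the block and only the arrays of the set, limma called 2544 for S59 at 7-10h, 6720 for S59 at 13-16h and 0 for lms at 7-10h (4947 at unadjusted p under 0.05), and kept the other 6 of 9. Gene lists and the mean of a gene's probes were not run for want of gene names. Low signal over background limits the size of differences, since 37.6% to 51.8% of values in a set lay below 2 times its lowest.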

Other observations

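The test in this part was chosen after the group of probes had been seen. A group of 313 probes moved as 1 on all 54 arrays, with a median correlation of 0.992 with their common profile and a median slope of 1.002. The common profile was highest in the Duf inputs at 10-13h, at 3.57 on the log2 scale, and lowest in the lms inputs at 13-16h, at -3.50. It was positive in every Duf group, the lowest being IP at 13-16h at 1.22. In S59 it was positive only in IP at 7-10h (1.32), and in lms only at 10-13h (1.29 in input and 0.94 in IP). The brightness of the group came in steps: 93.3% of it lay in 8 narrow steps of 0.30 on the log2 scale, with 34 to 40 probes each, against at most 42.5% in 100 random draws of probes of like brightness. Control RNA added at a few fixed amounts and read by copies of a few probes is a candidate explanation, and it would move with the amount of embryo RNA in each labelling. In that case the labelling differed along with the population, and its effect on the population differences was not tested. The next largest number of neighbours of a probe outside the group was 45, against 231 within it. Kept in the tests, 291 of these probes were called higher in IP in S59 at 7-10h, 233 lower in the Duf mean over windows, and 251 and 218 higher in S59 and in lms than in Duf. Control probes near the lowest intensities would not have been found in this way, and some may remain among the 44550.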
